A study of Homo sapiens with 6 samples.

How the data were processed

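Gene expression was measured by RNA sequencing in 6 samples of the human oesophageal squamous carcinoma line KYSE410, 3 controls and 3 with ADAR1 knocked down. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was captured on oligo-dT beads, and cDNA fragments of about 370 to 420 bp were selected. The protocol names no step that marks the strand. CASAVA, fastp and HISAT2 2.0.5 are named in the submitters' processing notes, with no role or order. The counting tool, the genome build and the annotation are not given in the sources used here. All 58735 gene coordinates in the deposited table were identical to those of GENCODE release 29 on GRCh38, and coordinates are given on that build.

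The deposited counts are whole numbers of reads per gene with no normalization, per the file headers and the values. Deposited FPKM values (fragments per kilobase per-million) were given per library and as group means, per the file headers. In each library the count divided by gene length and FPKM was constant over genes, at 0.966 to 0.97 of the count total in the control libraries and 1.05 to 1.06 in siADAR1. The FPKM therefore carried a library factor set by the authors. The authors' group means equalled the means over the 3 libraries and were not used further. Each table column was assigned to a sample by its group and replicate number as in the sample title, and 0 columns were left without a sample. Group and replicate number came from the titles.

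Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10, which left 15294, and 28008 of the 58735 genes had no count in any library. Library sizes were scaled by trimmed mean of M-values (TMM), with factors of 0.957, 0.96 and 0.963 in control and 1.05, 1.04 and 1.04 in siADAR1. The main test was the robust quasi-likelihood F test with group as the single term, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The common biological coefficient of variation was 0.123. Levels are CPM on the scaled library sizes, given as mean ± SD over 3 libraries per group. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. A fold against a group with 0 counts was bounded by a floor of 3 counts over that group, and a library value by a floor of 3 counts, or 0.173 to 0.198 CPM on unscaled library totals. Reads carry no molecular identifiers, so the floors cover counting error only.

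Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 25 of 29 lists that had at least 5 tested members. With an estimated correlation, used as an alternative, camera takes only the few residual degrees of freedom of the 6 libraries. It then has little power, so a call lost there does not show that correlation between genes explains the result. Members were counted as higher or lower at an adjusted p below 0.05 over all tested genes, and again adjusted over the list alone. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated. The rule named ADAR, BIRC3 and C16orf46. It added the 10 largest rises and 10 largest falls among protein-coding genes that passed the test, had a mean of at least 2 CPM and did not overlap between groups. It also added the 5 members with the smallest p in the interferon-stimulated, NF-kB target and pyroptosis lists and 2 members of every other list. Genes named for other lists could be left out where no member passed, and 1 gene that the rule named is not reported here.

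The alternatives were size factors from the relative log expression method, library totals alone, DESeq2 1.42.0, limma-voom, 2 other filters on low counts, the replicate number as a block, leaving out each library in turn, limma-trend on the deposited FPKM with a pseudocount of 0.1 or 1 and genes with a mean of at least 0.5, the same with a pseudocount of 1 and no filter, protein-coding genes alone, an estimated correlation in camera, and the rotation test fry. Leaving out both libraries numbered 1, and leaving ADAR out of the RNA editing list, were added after seeing the data. Pairs of libraries within a group differed by more than counting noise, with a chi-square per degree of freedom of 3.95 to 18.0 over genes with at least 20 counts, so no pair was treated as 1 library entered again, which does not show that the cultures were separate. All labels carried the same batch value, so no batch term was fitted.

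The gene test was tested on data simulated from the library sizes, mean levels and dispersions of these libraries. In 5 simulations, 200 of 15294 genes were changed. The test recovered 40.8% of genes changed 1.5-fold, 78.4% of those changed 2-fold and 94.6% of those changed 4-fold, and 6.8% of its calls were false. In the real data 7804 genes were called, far more than were changed here, so these shares need not hold for the real comparison. A simulated list of raised genes was called with a camera adjusted p of 1.13e-10, and 0 of 20 random lists were called. Genes were simulated independently of each other, so the list simulation cannot show whether the preset correlation suits the real lists.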

Results

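RNA from 6 samples of KYSE410, a cell line established from an oesophageal squamous cell carcinoma, was sequenced after selection of polyadenylated RNA. In 3 samples ADAR1, the enzyme that converts adenosine to inosine in double-stranded RNA, had been knocked down (siADAR1), and 3 samples were controls. The titles name the controls NC, and other labels call them control or wildtype, without saying whether they received a treatment of their own. If they received none, effects of siRNA delivery cannot be told apart from those of ADAR1 loss in any result below. Off-target effects of the siRNA cannot be told apart either. Total counts per library were 17329443, 15497788 and 15834849 in control replicates 1 to 3 and 16903792, 15175619 and 15203807 in siADAR1 replicates 1 to 3. Of 58735 annotated genes, 15294 had enough counts to be tested. No label says that the samples came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

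The series title places ADAR1 in radiosensitivity, through pyroptosis, cIAP2, NF-kB and editing of C16orf46 RNA. The single comparison was siADAR1 against control, and the knockdown target was examined first. ADAR (ENSG00000160710, chromosome 1, 154582057 to 154628013, GRCh38) was lower in each of the 3 siADAR1 libraries, at 92.8, 95.7 and 77.6 counts-per-million (CPM), than in any control library. Its mean was 443.6 ± 12.1 CPM (SD, n = 3) in control and 88.7 ± 9.72 CPM (SD, n = 3) in siADAR1, or 20% of control. The log2 fold change was -2.32 ± 0.09 (SE), with an edgeR quasi-likelihood adjusted p of 1.06e-08.

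**Figure D1:**
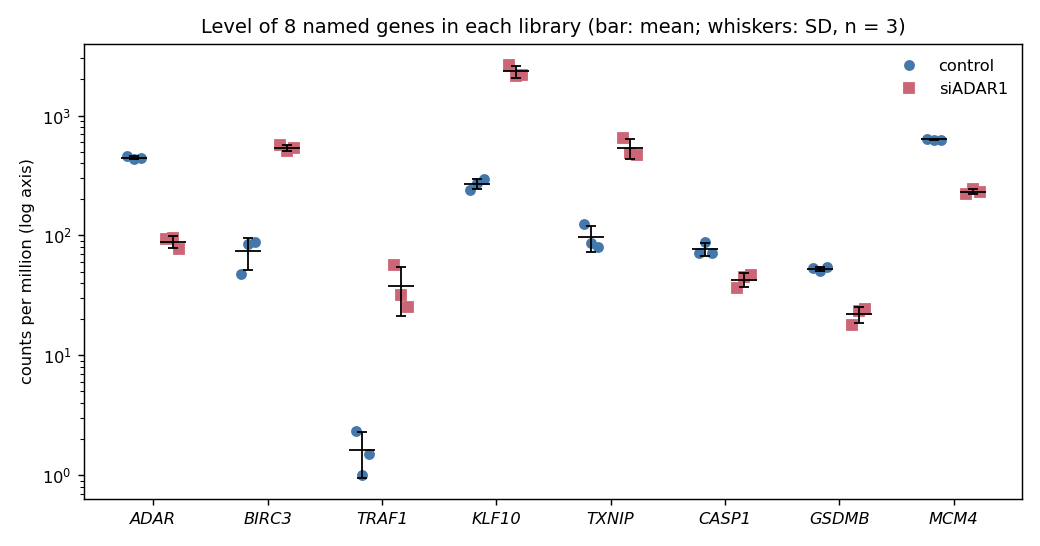
Counts-per-million (CPM) on a log axis for 8 named genes in each of the 3 control (circles) and 3 siADAR1 (squares) libraries, with the mean as a bar and the SD as whiskers. ADAR, CASP1, GSDMB and MCM4 were lower in every siADAR1 library than in any control library, and BIRC3, TRAF1, KLF10 and TXNIP were higher.

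Expression changed widely. At an adjusted p below 0.05, 7804 genes changed (51.0% of those tested), of which 3973 were higher and 3831 lower in siADAR1. A change of at least 2-fold was called for 2262 genes, 1506 higher and 756 lower. The groups did not overlap in CPM for 60.3% of tested genes, where chance gives 10%. Among genes with a mean of at least 100 CPM, 484 rose and 1021 fell, with a median log2 fold change of -0.17, while 1033 rose and 610 fell between 1 and 10 CPM (median 0.11) and 179 rose and 77 fell below 1 CPM (median 0.14). Scaling by library totals alone, without a composition factor, moved the median of all genes up by 0.12 and the split to 4892 higher and 2887 lower (62.9% higher against 50.9%). The libraries numbered 1 stood apart. On the first principal component, which held 71.3% of the variance, siADAR1 replicate 1 lay at 60.5 against 41.0 and 40.9 for the other siADAR1 libraries. On the second, with 11.7%, control replicate 1 lay at 36.1 against -19.6 and -13.3, and siADAR1 replicate 1 at 15 against -8.07 and -10. With both of these libraries left out, an alternative chosen after seeing the data, 8269 genes changed, 4162 higher and 4107 lower.

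**Figure D2:**
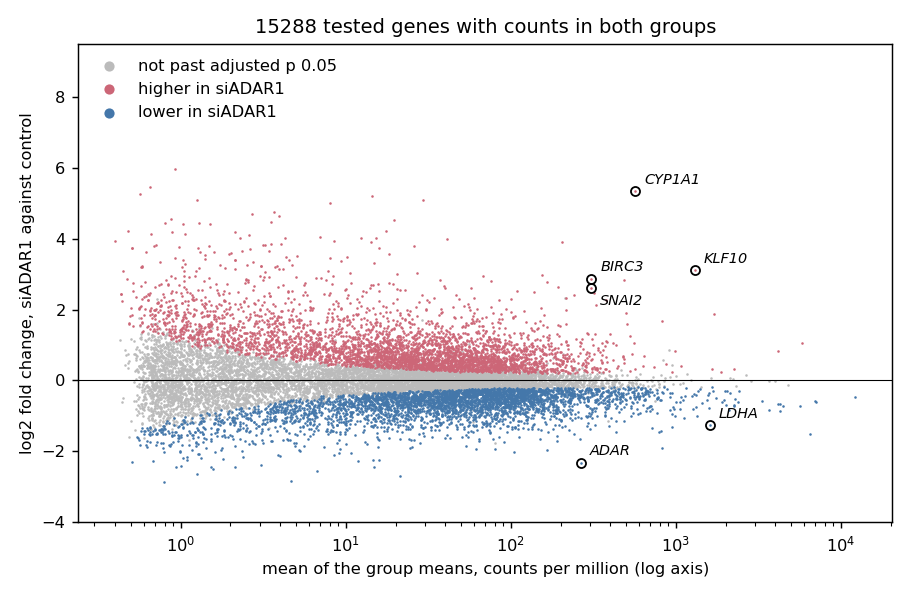
Log2 fold change of siADAR1 against control (vertical axis) against the mean of the group means in CPM (horizontal log axis) for tested genes, leaving out 6 with no count in one whole group. Red and blue points passed an adjusted p of 0.05 in the higher and lower direction, and 6 named genes are circled, with ADAR at -2.32 and CYP1A1 at 5.34.

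Most genes induced by NF-kB were higher in siADAR1. BIRC3 (ENSG00000023445, chromosome 11, 102317450 to 102339403), which encodes the ubiquitin ligase cIAP2, rose from 73.6 ± 22.5 to 539.9 ± 31.7 CPM (SD, n = 3 each). Its log2 fold change was 2.88 ± 0.23 (SE), with an adjusted p of 3.75e-05 in edgeR. Of 36 tested NF-kB target genes, 25 rose, 4 fell and 7 did not pass, with a median log2 fold change of 1.02. Adjusted over the list alone, 25 rose and 5 fell. TRAF1, an adaptor of tumour necrosis factor receptors, rose by 4.52, the chemokine genes CXCL3 and CXCL1 by 3.04 and 2.39, BCL3 by 2.29, the inhibitor gene NFKBIE by 2.06 and BIRC2, which encodes cIAP1, by 1.04. TNF, chosen after its values were seen, had 0 counts in the controls and 47 in the siADAR1 libraries, at least 14.9-fold higher against a floor of 3 counts over the control group. The median of the list was the same with TNF placed at that bound. The list ranked above other genes (camera adjusted p = 7.09e-11), and the call was lost with adjusted p = 0.18 with an estimated correlation. Among 26 NF-kB pathway components, 10 rose and 4 fell, the same counts as adjusted over the list alone, with a median of 0.23 (0.348 with library totals alone). MAP3K14, the kinase NIK of the non-canonical pathway, rose by 1.54 ± 0.11 (SE) and TAB3 by 1.29 ± 0.11 on the log2 scale. The components ranked above other genes with a camera adjusted p of 7.11e-03 (adjusted p = 0.30 with an estimated correlation).

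Interferon-stimulated genes moved in both directions. Of 45 tested, 12 rose, 10 fell and 23 did not pass, the same counts as adjusted over the list alone, and the median log2 fold change was 0.03. Over all 15294 tested genes, 3973 rose and 3831 fell, so the counts of this list lay near the general share. IRF1 (log2 fold change 1.76 ± 0.11, SE), EPSTI1 (1.63 ± 0.12), IRF7 (1.15 ± 0.16) and DDX60L (0.77 ± 0.11) rose, while OAS3, a synthetase activated by double-stranded RNA, fell from 114 ± 5.28 to 62.2 ± 4.33 CPM (SD, n = 3). The list did not rank apart from other genes (camera adjusted p = 0.765), and without control replicate 2 the number of its genes that rose was 7. The median turned to -0.0881 without control replicate 1, -0.00644 without control replicate 2 and -0.106 without siADAR1 replicate 1. Of 18 genes for sensing double-stranded RNA, 5 rose and 4 fell, again near the general share. The counts were the same when adjusted over the list alone, with a median of 0.17 and a camera adjusted p of 0.429. That median was 0.0716 without control replicate 1 and 0.29 with library totals alone, and the list passed with the rotation test fry (adjusted p = 0.00707, range 0.00707 to 0.552). The kinase gene IKBKE rose by 1.72 ± 0.11 (SE), and PRKRA, which encodes an activator of the kinase PKR, had a log2 fold change of -1.11 ± 0.11. None of the 21 type I and III interferon genes had enough counts to be tested, and the highest library value in that list was 1.15 CPM on the unscaled library total. Among these, chosen after their values were seen, IFNB1 had 0 counts in each control library and 4, 1 and 3 in siADAR1, IFNL1 had 0, 0 and 1 in control and 2, 7 and 0 in siADAR1, and IFNE had 20, 4 and 10 in control and 14, 8 and 8 in siADAR1.

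Pyroptosis and inflammasome genes included more falls than rises. Of 21 tested, 7 fell, 2 rose and 12 did not pass, the same counts as adjusted over the list alone. GSDMB, a gasdermin gene, had a log2 fold change of -1.27 ± 0.13 (SE), CASP1, which encodes the inflammasome protease, of -0.85 ± 0.12, IL1B of -0.76 ± 0.13 and GSDME, which encodes a gasdermin cleaved by caspase-3, of -0.48 ± 0.11. TXNIP, a regulator of thioredoxin and glucose uptake, rose by 2.48 ± 0.20, from 96.5 ± 24.2 to 536.8 ± 103.6 CPM (SD, n = 3). The median was -0.12, and 9.07e-05 with library totals alone, and the list did not rank apart (camera adjusted p = 0.307). Without control replicate 1 the number that rose was 5. Gene counts do not measure protein cleavage or cell death, so these values do not show whether pyroptosis changed. Of 29 apoptosis regulators, 11 rose and 6 fell, also when adjusted over the list alone. The BH3-only genes BMF and PMAIP1 rose by 1.91 ± 0.15 and 1.55 ± 0.12. The median of this list was -0.10, its mean 0.15 and its camera direction upward, with an adjusted p of 0.359, and the median turned to 0.02 with library totals alone and to 0.00805 without control replicate 2. With fry the apoptosis list passed (adjusted p = 2.93e-04, range 2.93e-04 to 0.429), as did the pyroptosis list (0.0183, range 0.0183 to 0.945).

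C16orf46 (ENSG00000166455, chromosome 16, 81053497 to 81077267) was not measurable at this depth. It had 2, 0 and 2 counts in the controls and 0, 0 and 1 in the siADAR1 libraries, each below the floor of 3 counts per library, and no fold change is given. Gene counts hold no information on editing. Of 19 genes for RNA editing and double-stranded RNA binding, ADAR included, 10 fell and 2 rose, also when adjusted over the list alone, with a median log2 fold change of -0.31. DGCR8, a partner of the nuclease Drosha in microRNA processing, had a log2 fold change of -1.10 ± 0.09 (SE). The number that rose was 1 when any library but control replicate 1 was left out, and the median was -0.17 without a filter on low counts, -0.18 with DESeq2 and -0.191 with library totals alone. The list ranked below other genes with a camera adjusted p of 2.94e-05 (adjusted p = 0.18 with an estimated correlation). With ADAR, whose fall the knockdown set, left out of the list, an alternative chosen after seeing the data, 9 of 18 fell and 2 rose, with a median of -0.237 and a camera adjusted p of 1.65e-03 (adjusted p = 0.29 with an estimated correlation). Of 29 transcripts known to be edited by ADAR enzymes, 13 fell and 3 rose, also when adjusted over the list alone. Their median was -0.23, 8 fell with a median of -0.114 with library totals alone, and the list did not pass (camera adjusted p = 0.064), but passed without a filter on low counts, at 0.02, and with the rotation test fry, at 0.00707, within a range of 0.00707 to 0.355 over all alternatives. F11R and BLCAP were the members with the smallest p, at -0.63 ± 0.10 and -0.47 ± 0.08.

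**Figure D3:**
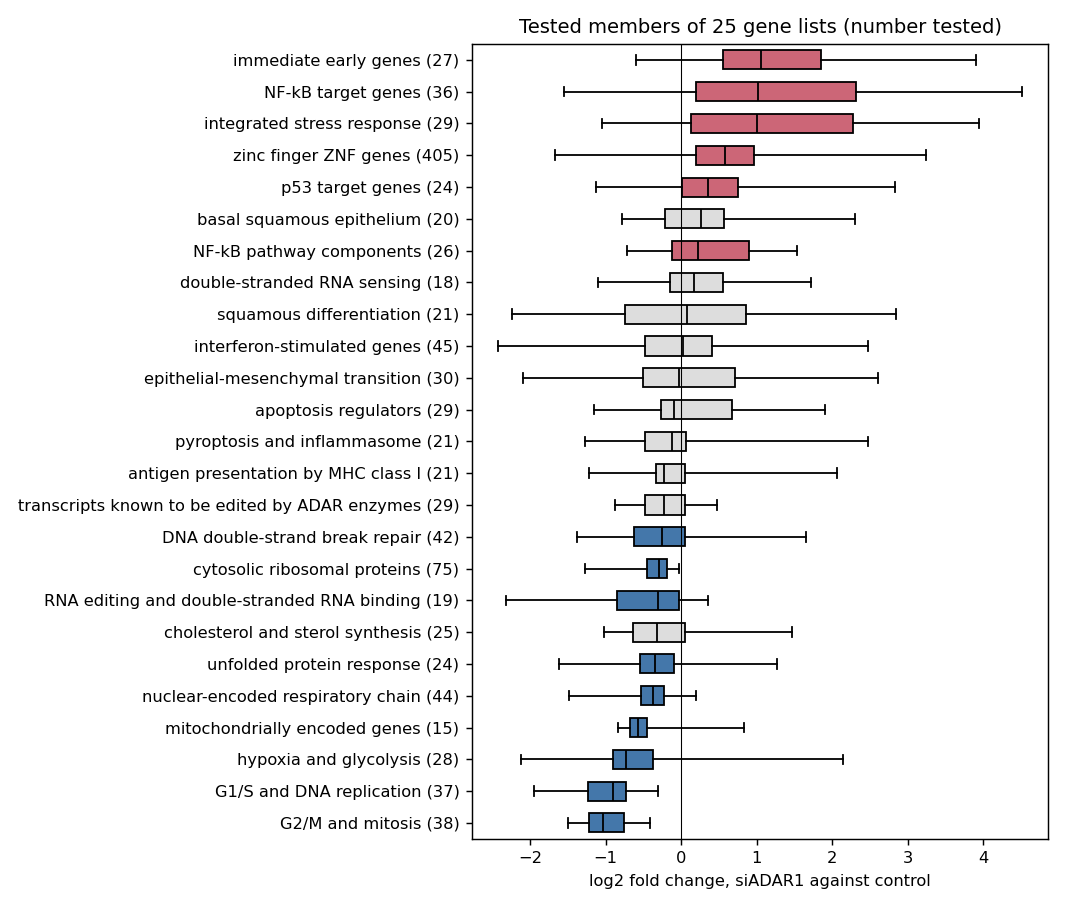
Log2 fold change of siADAR1 against control for the tested members of 25 gene lists, with the median as a line, quartiles as the box and the full range as whiskers. Red and blue lists passed a camera adjusted p of 0.05 in the higher and lower direction, grey lists did not and TNF is drawn at its bound, while medians ran from -1.04 for G2/M and mitosis to 1.06 for immediate early genes, and no list passed with an estimated correlation.

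Most genes of the cell division cycle fell. Of 37 tested genes for G1/S and DNA replication, 35 fell and 0 rose, and 37 fell when adjusted over the list alone, with a median log2 fold change of -0.91. GINS1, a subunit of the replicative helicase, went from 127 ± 4.48 to 33.2 ± 1.44 CPM and MCM4, another helicase subunit, from 631 ± 3.06 to 231 ± 11.1 CPM (SD, n = 3). The list ranked below other genes (camera adjusted p = 7.74e-25, and adjusted p = 0.19 with an estimated correlation). Of 38 genes for G2/M and mitosis, 35 fell and 0 rose, also when adjusted over the list alone, with a median of -1.04. PLK1, a mitotic kinase, had a log2 fold change of -1.39 ± 0.10 (SE) and UBE2C, an enzyme that marks cyclins for degradation, of -1.27 ± 0.10. The camera adjusted p was 9.82e-20 (adjusted p = 0.30 with an estimated correlation). Of 24 p53 target genes, 11 rose and 5 fell, also when adjusted over the list alone, with a median of 0.36 (camera adjusted p = 7.11e-03, and adjusted p = 0.42 with an estimated correlation). GDF15 rose by 1.77 ± 0.13 and SESN2 by 1.79 ± 0.15, both of which are also induced by ATF4. The p53 median was 0.547 without siADAR1 replicate 2, and the number that fell was 3 without siADAR1 replicate 2, without siADAR1 replicate 3 or with library totals alone. Of 42 genes for repair of DNA double-strand breaks, 19 fell and 4 rose, also when adjusted over the list alone, with a median of -0.25. H2AFX, which encodes the histone variant phosphorylated at breaks, had a log2 fold change of -1.38 ± 0.09, and RAD52 rose by 1.65 ± 0.15, while 7 genes of the list rose with library totals alone, with a median of -0.137. The repair list ranked below other genes with a camera adjusted p of 4.02e-03 (adjusted p = 0.42 with an estimated correlation).

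Lists of stress-responsive genes moved in different directions. Of 29 genes of the integrated stress response, the programme driven by ATF4, 19 rose and 4 fell, with 20 and 4 when adjusted over the list alone, and the median log2 fold change was 1.01. CHAC1, which degrades glutathione, rose from 9.24 ± 2.47 to 65.6 ± 8.60 CPM and DDIT3, which encodes the transcription factor CHOP, from 16.4 ± 1.47 to 81.1 ± 13.3 CPM (SD, n = 3). The number that fell was 2 without siADAR1 replicate 3 or with library totals alone. The list ranked above other genes with a camera adjusted p of 1.09e-10 (adjusted p = 0.32 with an estimated correlation). Of 27 immediate early genes, 17 rose and 1 fell, with 17 and 2 when adjusted over the list alone, and the median was 1.06. KLF10 rose by 3.11 ± 0.11 (SE), from 269 ± 26.6 to 2328 ± 283 CPM (SD, n = 3), and IER2 rose by 1.63 ± 0.09. The number that fell was 3 without control replicate 1 and 2 without siADAR1 replicate 3. The camera adjusted p was 3.38e-10 (adjusted p = 0.18 with an estimated correlation). The unfolded protein response of the endoplasmic reticulum went the other way, with 13 of 24 genes lower and 5 higher, also when adjusted over the list alone, and a median of -0.34 (-0.223 with library totals alone). SEC61B, a subunit of the translocation channel, had a log2 fold change of -1.62 ± 0.12 and the disulfide isomerase gene PDIA6 of -0.87 ± 0.09. This list had a camera adjusted p of 0.0224 (adjusted p = 0.36 with an estimated correlation).

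In lists of metabolic and ribosomal genes, more members fell than rose. Of 28 genes of hypoxia and glycolysis, 20 fell and 4 rose, with 21 and 4 when adjusted over the list alone, and the median log2 fold change was -0.73 (camera adjusted p = 1.21e-05, and adjusted p = 0.30 with an estimated correlation). LDHA, lactate dehydrogenase A, went from 2258 ± 199 to 937 ± 152 CPM (SD, n = 3), while VEGFA, which encodes an angiogenic growth factor, rose by 2.14 ± 0.13 (SE). Of 75 cytosolic ribosomal protein genes, 52 fell and 0 rose, with 56 lower when adjusted over the list alone, and the median was -0.29. RPS15 had a log2 fold change of -1.28 ± 0.09 and RPL7A of -0.87 ± 0.09. With library totals alone 33 of the ribosomal protein genes fell, with a median of -0.174. The list had a camera adjusted p of 7.36e-08 (adjusted p = 0.42 with an estimated correlation). Of 44 nuclear-encoded respiratory chain genes, 30 fell and 0 rose, also when adjusted over the list alone, with a median of -0.38 and 19 lower with library totals alone. COX6C and ATP5F1A had log2 fold changes of -1.48 ± 0.12 and -0.91 ± 0.08, with a camera adjusted p for the list of 7.90e-06 (adjusted p = 0.42 with an estimated correlation). Of 15 mitochondrially encoded genes, 11 fell and 2 rose, with 12 and 2 when adjusted over the list alone, and a median of -0.57. MT-ATP6 had a log2 fold change of -0.84 ± 0.10, and MT-RNR2, a ribosomal RNA, rose by 0.83 ± 0.08. On FPKM (fragments per kilobase per-million) without a filter both calls were lost, with adjusted p of 0.185 for MT-ATP6, within a range of 1.92e-25 to 0.185, and of 0.0508 for MT-RNR2, within 3.75e-25 to 0.0508. The log2 fold changes barely moved there, at -0.85 for MT-ATP6 and 0.82 for MT-RNR2. The number of mitochondrially encoded genes that rose was 1 without control replicate 2, control replicate 3, siADAR1 replicate 1 or siADAR1 replicate 3. The camera adjusted p was 7.54e-03 (adjusted p = 0.44 with an estimated correlation). Of 25 genes for cholesterol and sterol synthesis, 12 fell and 5 rose, also when adjusted over the list alone, with a median of -0.32 (-0.202 with library totals alone). The sterol list did not pass (camera adjusted p = 0.0656), but passed without control replicate 3, at 0.0312, without a filter on low counts, at 0.0139, and with fry, at 0.0183, within a range of 0.0139 to 0.417 over all alternatives. ACAT2 went from 50.6 ± 2.83 to 25.3 ± 1.09 CPM (SD, n = 3), and DHCR7, the last enzyme of cholesterol synthesis, had a log2 fold change of -0.89 ± 0.12.

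Zinc finger genes of the ZNF series, most of which encode DNA-binding proteins, formed the largest list. Of 405 tested, 229 rose, 21 fell and 155 did not pass, with 235 and 21 when adjusted over the list alone. The median log2 fold change was 0.58, with quartiles of 0.20 and 0.97. ZNF671 rose from 5.86 ± 0.91 to 35.1 ± 6.18 CPM and ZNF697 from 42.0 ± 5.31 to 159 ± 23.4 CPM (SD, n = 3). The list ranked above other genes with a camera adjusted p of 7.32e-12 (adjusted p = 0.18 with an estimated correlation).

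Lists for the epithelial state held genes that moved both ways and did not pass. Of 20 basal squamous genes, 9 rose and 4 fell, with 10 and 4 when adjusted over the list alone, a median log2 fold change of 0.26 and a camera adjusted p of 0.112. NGFR rose by 2.31 ± 0.18 (SE) and BNC1, a transcription factor of basal keratinocytes, by 1.16 ± 0.10. The basal list passed without a filter on low counts (adjusted p = 0.0269), without both libraries numbered 1 (0.0372) and with fry (0.00158), within a range of 0.00158 to 0.324 over all alternatives, and 2 of its genes fell without control replicate 3. Of 21 genes for squamous differentiation, 9 rose and 7 fell, also when adjusted over the list alone, with a median of 0.08 and a camera adjusted p of 0.309. This median was 0.028 without siADAR1 replicate 3, 0.128 without siADAR1 replicate 1 and 0.132 without control replicate 2 or siADAR1 replicate 2. It was 0.195 with library totals alone, 0.291 without a filter on low counts, 0.294 with a stricter filter, 0.179 with DESeq2, and 0.282 and 0.268 on FPKM with pseudocounts of 0.1 and 1. The transcription factor gene KLF4 rose by 2.26 ± 0.15, and keratin gene KRT6A had a log2 fold change of -2.24 ± 0.20. Of 30 genes for epithelial-mesenchymal transition, 9 rose and 10 fell, also when adjusted over the list alone, with a camera adjusted p of 0.571. The median of that list was -0.03, against a mean of 0.14 and an upward camera direction, and it turned to 0.09 with library totals alone, and to 0.00525, 0.0328, 0.109 and 0.00147 without control replicate 1, control replicate 3, siADAR1 replicate 1 and siADAR1 replicate 3. SNAI2, which encodes the repressor Slug, rose from 86.5 ± 10.4 to 525 ± 42.7 CPM (SD, n = 3). Of 21 genes for antigen presentation by MHC class I, 7 fell and 3 rose, also when adjusted over the list alone, with a median of -0.22 and a camera adjusted p of 0.359. CD274, which encodes PD-L1, rose by 2.07 ± 0.15, and the peptide transporter gene TAP2 had a log2 fold change of -1.22 ± 0.11. Without control replicate 2 or with library totals alone, the number of these genes that fell was 4, and with library totals alone the median was -0.104. With fry the squamous differentiation list (adjusted p = 0.00459, range 0.00459 to 0.417) and the MHC class I list (0.0206, range 0.0206 to 0.506) passed.

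Among protein-coding genes with a mean of at least 2 CPM and no overlap between groups, the largest rise was that of CYP1A1, a cytochrome P450 enzyme gene induced through the aryl hydrocarbon receptor, at a log2 fold change of 5.34 ± 0.80 (SE, adjusted p = 6.30e-03 in edgeR). Its level was 1848 CPM in siADAR1 replicate 1, against 774 and 700 CPM in replicates 2 and 3 and 27.2 ± 18.8 CPM (SD, n = 3) in control. Without control replicate 1 the log2 fold change of CYP1A1 was 6.07, and without siADAR1 replicate 1 it was 4.75. SPNS2, a sphingosine-1-phosphate transporter gene, rose by 5.21, NEURL3 by 5.11, RIPOR3 by 5.02, KMO by 4.75, DMBT1 by 4.71, HDGFL1 by 4.46 and ADM2 by 4.22. KMO, DMBT1 and HDGFL1 had control means of 0.257, 0.183 and 0.296 CPM, close to the floor of 3 counts, which was 0.173 to 0.198 CPM. The controls of DMBT1 stood at 0.483, 0 and 0.0657 CPM, so without control replicate 1 they lay under the floor and no fold is given, and without siADAR1 replicate 1 its log2 fold change was 4.02. The DMBT1 call was lost on FPKM without a filter (adjusted p = 0.0508, within a range of 2.04e-23 to 0.0508 over all alternatives). The histone gene HIST2H4B rose by 4.18 ± 1.09, but it shares its coding sequence with HIST2H4A, so its reads are uncertain. Its log2 fold change was 3.02 without siADAR1 replicate 2, and without control replicate 2 the controls lay under the floor, so no fold is given. That call was lost without control replicate 1 (adjusted p = 0.0695), without control replicate 3 (0.0541), without both libraries numbered 1 (0.261) and on FPKM without a filter (0.139), within a range of 1.35e-07 to 0.261 over all alternatives. The largest fall among the same genes was that of the kinase gene LCK, from 8.18 ± 3.82 to 1.15 ± 0.33 CPM (SD, n = 3). CDH6, a cadherin gene, had a log2 fold change of -2.69 ± 0.16, SCD5 of -2.46 ± 0.19, the insulin receptor gene INSR of -2.45 ± 0.40, CSPG4 of -2.39 ± 0.35, CACNG7 of -2.28 ± 0.21, CA12, a carbonic anhydrase gene, of -2.24 ± 0.21 and RASSF2 of -2.15 ± 0.49. Without siADAR1 replicate 2 that of RASSF2 was -3.28, and without both libraries numbered 1 that of LCK was -2.23.

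Most markers of other cell types had too few counts to be tested. Of 13 fibroblast markers, 4 were tested, of which 3 rose, also when adjusted over the list alone, among them LUM, from 35.0 ± 6.51 to 58.0 ± 6.15 CPM, and FAP, from 0.21 ± 0.18 to 1.05 ± 0.25 CPM (SD, n = 3). Of 20 immune cell markers, CD8A and CSF1R were tested and both rose, also when adjusted over the list alone, to 3.03 ± 0.52 and 0.73 ± 0.14 CPM. On FPKM with a filter, 1 fibroblast and 1 immune marker rose. Of 10 endothelial markers VWF alone was tested, at 0.91 ± 0.41 CPM in control and 0.86 ± 0.45 CPM in siADAR1 (adjusted p = 0.895). Its log2 fold change of -0.10 turned to 0.02 with library totals alone, 0.29 without control replicate 2 and 0.30 without siADAR1 replicate 1.

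Across the 25 lists with at least 5 tested members, 6 ranked above and 9 below other genes with a preset correlation of 0.01, and 0 of the 25 passed in camera with an estimated correlation, where 5 had an unadjusted p under 0.05 and the smallest adjusted p was 0.18. Immediate early genes stayed at 0.18 although their estimated correlation was 0.084. Among the lists called at the preset, the estimate ran from 0.03 for ZNF genes to 0.64 for mitochondrially encoded genes. It was 0.52 for G2/M and mitosis, 0.50 for the integrated stress response, 0.49 for ribosomal proteins and 0.43 for G1/S and DNA replication. The version with an estimated correlation rests on few residual degrees of freedom, so its lost calls alone do not tell whether correlation between genes explains a list's rank. Where the genes of a list correlate above the preset, its camera p at the preset is too small. By how much was not tested. The rotation test fry, which asks whether a list's genes moved one way on balance, passed 23. Among the 83 distinct named genes, 10 overlap another annotated gene that holds at least 10% as many counts, namely SPNS2, KMO, DDX60L, PRKRA, DDIT3, ACAT2, DGCR8, MT-ATP6, COX6C and CSF1R, and their values are uncertain. For MT-ATP6 the overlap, with MT-CO3, is on the same strand, and for the others it is on the opposite strand, where no source used here says that the counting used strand.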

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

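Leaving out both libraries numbered 1, and ADAR from the RNA editing list, was chosen after seeing the data. The 7804 changed genes stayed within 1.5 times under every alternative, from 5879 (FPKM without a filter) to 8582 (replicate block), and between 6737 and 7852 with 1 library left out. DESeq2 also called 7138 of them (91.5%), all in the same direction, and limma-voom 7687. The count of genes changed at least 2-fold (2262) moved to 919 (595 higher, 324 lower) on FPKM with a pseudocount of 1 and to 876 (570 higher, 306 lower) without a filter. With a pseudocount of 0.1 it was 1785, so the step to 919 came with the pseudocount, and the cause of the rest was not tested. With the replicate number as a block, 8582 genes were called. Deviations of same-numbered libraries from their group means correlated at 0.25, 0.084 and 0.11 over genes, and since 0.084 lay under 0.1 the numbers were not taken to pair the samples. The cut-off of 0.1 was a choice, and an effect shared by same-numbered libraries is not excluded. Control replicate 2 correlated best with siADAR1 replicate 3, and every other library with its own number. The block changed no list or named gene call. ADAR (-2.38 to -2.23) and BIRC3 (2.63 to 3.02) kept their calls with any library left out. The 15 lists past the threshold kept their calls in the other 13 settings (largest adjusted p = 0.0409), but 0 passed with an estimated correlation, the NF-kB target median staying at 1.02 (adjusted p = 0.179), and 23 passed with fry, which asks another question. Few residual degrees of freedom limit the test with an estimated correlation. With fry the pyroptosis list, median -0.118, passed at 0.0183, as did 7 other lists that camera did not call. Medians of 4 lists that camera did not call changed sign, and except with library totals alone the cause was not tested. The interferon-stimulated median was -0.0164 without a filter, -0.106 to 0.0671 with 1 library left out and -0.0841 without both libraries numbered 1. Scaling by library totals alone moved genes up by a median of 0.12, which accounts for the changes of sign in that setting. The medians were then 9.07e-05 for pyroptosis, 0.0219 for apoptosis regulators and 0.0897 for epithelial-mesenchymal transition. The apoptosis median ran from -0.157 to 0.00805 with 1 library left out. The epithelial-mesenchymal median ran from -0.0387 to 0.109, and was 0.0933 without a filter and 0.0557 without both libraries numbered 1. VWF, not called, went to 0.01991 with library totals alone, -0.38 to 0.30 with 1 library left out and 0.25 without both. Of 1475 values for the 83 named genes, 1464 kept their direction and side of the threshold 7 lost the call and 4, all of VWF, changed sign. C16orf46 gave no value under any alternative because it failed the filter or stayed below the floor of 3 counts, and depth likewise limits the interferon genes.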

Other observations

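The tests on nuclear RNA, on replicate 1 and on the histone genes were chosen only after the results were seen, as were the genes and classes described next. Other genes linked to the aryl hydrocarbon receptor, looked at because of CYP1A1, moved in both directions and were not tested as a list. CYP1B1 went from 72.3 ± 26.5 to 360.5 ± 146 CPM, TIPARP from 76.5 ± 12.8 to 408 ± 111 CPM and the receptor gene AHR from 80.1 ± 10.3 to 161.5 ± 19.2 CPM (SD, n = 3). AHRR had a log2 fold change of 0.37 (adjusted p = 0.323 in edgeR) and ALDH3A1 of -1.18 (adjusted p = 0.0734), NQO1 fell by 0.71, ALDH1A3 fell by 0.45 and NFE2L2 rose by 0.91 on the log2 scale. For CYP1A1, CYP1B1 and TIPARP, replicate 1 was the highest library in both groups, at 1848, 529 and 535.5 CPM in siADAR1 and 48.9, 102.8 and 90.9 CPM in control.

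Among long non-coding RNA genes that passed the test, more rose than fell, and most did not pass. Of 585 tested lincRNA genes, 183 rose and 29 fell, with a median log2 fold change of 0.50, and of 680 antisense genes 165 rose and 60 fell, although reads of antisense genes cannot be told from those of their partners without strand. Of 407 processed pseudogenes, 39 rose and 75 fell, with a median of -0.24, and with library totals alone 46 rose and 54 fell, with a median of -0.12. NEAT1, a nuclear RNA, rose by 1.29 ± 0.17 (SE), and MALAT1 had a log2 fold change of -0.15 ± 0.12. Genes often used as references were lower, with ACTB at -1.52, GAPDH at -0.67 and EEF1A1 at -0.58, and these directions held with library totals alone. The lincRNA genes took 0.258% to 0.26% of counts in control and 0.364% to 0.422% in siADAR1.

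The real grouping of the 6 libraries gave 7804 changed genes, and 1 of the 10 splits into 3 and 3, the real one, gave as many. The highest of the other splits gave 0. Every other split mixed control and siADAR1 libraries, which put the difference between them into the within-group spread. The 0 calls of those splits therefore do not show how many calls chance would give. With 10 splits, a share below 0.05 cannot be reached.

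The rise of 405 ZNF genes was set against properties of the genes and of the RNA. In 10000 random lists of other protein-coding genes matched on mean level, transcript length and GC content, the central 95% of medians lay between -0.01 and 0.14, and the ZNF median of 0.58 lay 0.518 above the median of these lists. These properties, with all 405 genes having a value, do not account for the whole rise. More nuclear or unspliced RNA in the siADAR1 libraries could also raise them and stays open, because 99 sense intronic genes had a median of -0.054 (0.0632 with library totals alone) with quartiles of -0.53 and 0.32 but a median level of 1.15 CPM, near the floor, while the lincRNA median was 0.50, NEAT1 rose and MALAT1 did not pass (-0.15, adjusted p = 0.312 in edgeR). An effect of ADAR1 loss on these genes is a hypothesis. It cannot be told apart from such a shift, or from an effect of the siRNA treatment itself, with counts alone.

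Changes were larger in siADAR1 replicate 1. Among 3442 genes called higher without that library, it lay above replicates 2 and 3 by a median of 0.15 on the log2 scale, and among 3383 called lower its median difference was -0.12. A stronger knockdown in replicate 1 had no support in ADAR RNA, which was lowest in replicate 3. The ADAR level was 92.8, 95.7 and 77.6 CPM in siADAR1 replicates 1 to 3. In replicate 1 it lay 0.11 (log2) above the mean of the other siADAR1 libraries but within their range. That explanation stays open, since each value rests on 1 library and ADAR1 protein was not measured here. Handling shared by the libraries numbered 1 also stays open, as their deviations correlated at 0.25 over genes, which are not independent, and the other same-numbered pairs at 0.084 and 0.11. No label separates these explanations.

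Most histone cluster genes rose while most replication genes fell. Of 25 tested, 18 rose and 0 fell, with a median log2 fold change of 1.81, and without both libraries numbered 1 the counts were 17 and 0. Their median level was 1.1 CPM in control, near the floor, and 4.1 CPM in siADAR1. The pseudogenes HIST2H2BC and HIST2H2BD were among those tested and did not pass. HIST1H2AC went from 4.80 ± 1.51 to 76.8 ± 14.6 CPM (SD, n = 3). More cells passing through S phase, when histone mRNAs are made, would raise the replication genes, but these had a median of -0.909 with quartiles of -1.2 and -0.73. These values were known before the prediction was written. They argue against more cells passing through S phase, but gene counts do not measure the share of cells in that phase and cannot exclude cells held there. Carry-over of RNA without poly(A) tails could raise the histone genes and stays open. The 19 small RNA genes had a median of -0.33, but at a median level of 0.796 CPM they lay too near the floor to decide. Of single genes, MT-RNR2 rose, while MALAT1 did not pass (log2 fold change -0.15, adjusted p = 0.312 in edgeR). A change in histone mRNA ends that leaves poly(A) tails is a further hypothesis that gene counts cannot test.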
